A study of Mus musculus with 12 samples.

How the data were processed

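Total RNA from 12 pools of 50 denuded germinal-vesicle oocytes (4 groups, 3 pools each) was extracted with a PicoPure kit, per the labels. Libraries were made with a SMARTer stranded total RNA kit after removal of ribosomal RNA, and were sequenced as 100 bp paired-end reads on an Illumina HiSeq. The submitters' processing notes name FastQC 0.11.7, STAR 2.7.0a with the mm10 genome, and edgeR without a version. The count table was deposited as raw counts per gene, which the authors restricted to genes above 1 CPM in at least 3 libraries. The signal table was deposited as CPM, counts scaled by library size and TMM factors. It equalled TMM-scaled CPM computed here from the counts within a relative 5.1e-15 and was used only for that check. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Gene symbols are therefore used as deposited. Of 11385 symbols, 11274 (99.0%) were located in GENCODE vM21, 574 of them under an older name.

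Groups were taken from the labels. The label of 1 pool gives a genotype spelled "Mn2-/-", and it was placed in Mfn2-/- by its description. The 7 comparisons are Mfn1-/-, Mfn2-/- and Mfn1&2-/- each against WT, Mfn1&2-/- against Mfn1-/- and against Mfn2-/-, Mfn1-/- against Mfn2-/-, and the interaction of the 2 losses. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 as a quasi-likelihood model with 1 mean per group, all 12 libraries and 8 residual degrees of freedom. filterByExpr kept all 11385 genes. Adjusted p-values are BH values over all genes of a comparison, and an adjusted p below 0.05 was called a change. Totals per library ran from 11575357 to 16024893 counts. A group without counts was given a bound that sets 3 counts in its place, and groups with 1 to 3 counts a ratio with a 95% counting interval.

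Genes named in each comparison are Mfn1, Mfn2 and the 10 called genes with the largest fold change in each direction, with a mean of at least 5 CPM in the higher group and no overlap between 3 and 3 libraries. Names of predicted genes and names changed into dates were left out of naming but still counted. For the interaction the mean had to reach 5 CPM in any group, and the overlap rule was not applied. From each gene list up to 4 members with the smallest p were added. Before the data were examined, 26 lists with 713 genes were fixed. They cover mitochondrial fusion and fission, ER-mitochondria contact, OXPHOS subunits, mtDNA maintenance, mitochondrial chaperones, integrated stress response, ER unfolded protein response, oocyte, maternal effect, meiotic maturation, mRNA storage, adhesion and contact, PI3K, sphingolipid, apoptosis, autophagy, antioxidant, glycolysis, cholesterol, ribosomal protein, vesicle and immediate early genes. They also hold markers of granulosa, of theca, and of endothelium, blood and immune cells (the endothelium list), and mtDNA-encoded transcripts. The table held 600 list entries but no theca marker and 0 mtDNA-encoded transcripts, so 24 lists were tested. Lists were tested with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, BH-adjusted over lists, and again with the correlation estimated. Counts "over the list alone" use BH over the members of the list.

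The edgeR, camera and DESeq2 p-values rest on 3 libraries per group. The edgeR fit was tested on a single simulated data set per comparison with WT, drawn from WT mean CPM. In each, 50 genes per fold were changed, all with at least 5 CPM in WT, so lower genes were not tested. The fit recovered 36 to 44% of 1.5-fold, 60 to 68% of 2-fold and 92 to 100% of 4-fold changes. False calls made up 1.96%, 4.43% and 7.98% of the calls for Mfn1-/-, Mfn2-/- and Mfn1&2-/- against WT. Alternatives were DESeq2 median-of-ratios scaling (RLE), library size only, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, no filter, at least 5 CPM in 3 libraries, the replicate number as a block, only the groups compared, a 1.5-fold threshold (glmTreat), and each library left out in turn. A fit without genes within 10 Mb of Mfn1 or Mfn2 and fits of 6 against 6 libraries were added after the data had been seen. Overlaps between comparisons were set against 20 simulated data sets without changes. Single exons and splicing were not analysed here.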

Results

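Total RNA was sequenced from germinal-vesicle oocytes, the stage held in meiotic prophase inside the follicle, after their cumulus cells had been removed. The mice were unprimed, 21 to 23 days old and labelled C57BL/6J. Mitofusins 1 and 2 are GTPases of the outer mitochondrial membrane that join mitochondria, and mitofusin 2 also tethers mitochondria to the ER. The 4 groups were WT, Mfn1-/-, Mfn2-/- and Mfn1&2-/-, with n = 3 libraries each and 50 oocytes in every library. Libraries held 11575357 to 16024893 counts over 11385 genes, and a floor of 3 counts stood at 0.188 to 0.253 CPM, counts scaled to library size. Values after ± are SD over the 3 libraries of a group for CPM. For log2 fold changes they are approximate standard errors, the absolute log2 fold change divided by the square root of edgeR's F statistic. Fold bounds and counting intervals rest on counts pooled over the libraries of a group, not on the mean CPM, and cover counting error only. The labels do not say whether the pools of a group came from separate animals or litters, so p-values measured the spread between pools. Libraries of a group correlated at 0.968 to 0.985 across genes. On the principal component with 27.5% of the variance, Mfn2-/- and Mfn1&2-/- libraries stood at 26.96 to 33.90, and WT and Mfn1-/- libraries at -35.8 to -24.2. On the component with 15.8%, Mfn2-/- libraries stood at 24.2 to 32.8 and Mfn1&2-/- libraries at -44.6 to -22.2. Positions are GRCm38 (mm10) gene spans from GENCODE vM21.

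Granulosa-cell transcripts stood high in WT replicate 3, where 9 of 12 measured markers had their highest value of the 12 libraries. Inhba, a subunit of activin and inhibin, reached 71.3 CPM there, 36.2 times the mean of the other 11 libraries. Inha reached 77.9 CPM (10.3 times) and Inhbb 155.4 CPM (26.3 times). Serpine2 was at 370.7 CPM there, only 1.10 times the others, so that marker said little about granulosa cells. Nr5a2 (1.36 times) and Cyp19a1 (1.46 times) were also highest there by little. Of the markers not highest there, Gata4 stood at 0.713 times the others, Fshr at 2.14 and Kitl at 1.37 times. The markers given with values were picked after these were seen.

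Mfn1 (chromosome 3, 32529465 to 32579239) stood at 279.7 ± 16.4 CPM in WT. It fell to 18.1 ± 0.696 CPM in Mfn1-/- (6.48% of WT; log2 fold change -3.94 ± 0.16; edgeR quasi-likelihood adjusted p = 7.83e-10) and to 20.1 ± 5.87 CPM in Mfn1&2-/- (7.19%; -3.80 ± 0.16; adjusted p = 6.14e-10). Mfn2 (chromosome 4, 147873599 to 147904704) stood at 76.3 ± 9.75 CPM in WT. It fell to 11.2 ± 2.19 CPM in Mfn2-/- (14.6% of WT; -2.77 ± 0.17; edgeR adjusted p = 7.57e-08) and to 10.8 ± 1.31 CPM in Mfn1&2-/- (14.1%; -2.83 ± 0.17). The other mitofusin was not called: Mfn2 was at 66.5 ± 3.74 CPM in Mfn1-/- (87.2% of WT; edgeR adjusted p = 0.643), and Mfn1 at 230.2 ± 14.2 CPM in Mfn2-/- (82.3%; edgeR adjusted p = 0.218). Each of the 6 libraries of a gene's knockout groups lay below each of the 6 others. Counts over a whole gene do not show which exons the remaining reads came from.

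**Figure D1:**
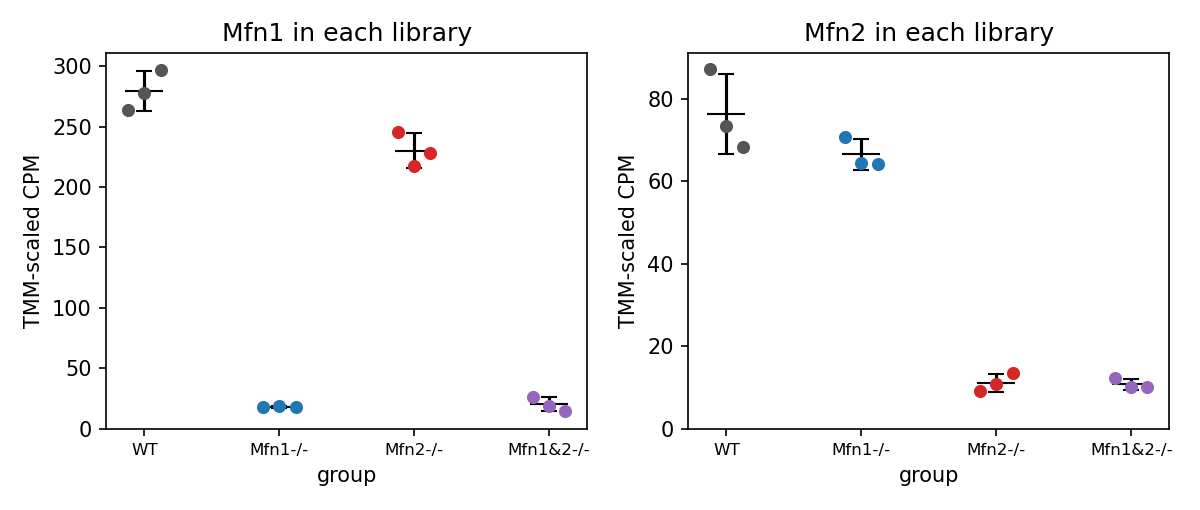
CPM of Mfn1 and Mfn2 in each of the 12 libraries by group. Points are libraries, and dashes with bars are group means with SD over 3 libraries.

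The comparison of Mfn1-/- with WT asked what loss of mitofusin 1 alone changed. By edgeR's quasi-likelihood test with BH correction, 26 of 11385 genes changed (8 higher, 18 lower), 16 of them more than 2-fold. Gli3, the transcription factor at the end of Hedgehog signalling, rose from 134.7 ± 52.2 to 354.2 ± 41.6 CPM (1.39 ± 0.22, edgeR adjusted p = 0.0159; chromosome 13, 15463235 to 15730026). Cdon, a Hedgehog coreceptor, rose (0.86 ± 0.16), as did Ocln, a tight-junction protein (1.02 ± 0.17), and Add3, which caps actin filaments (0.64 ± 0.11). Chst11, which sulfates chondroitin, fell from 35.5 ± 8.92 to 9.41 ± 3.48 CPM (-1.92 ± 0.25, edgeR adjusted p = 0.00582; chromosome 10, 82985498 to 83195900). Fgf10, a growth factor, also fell (-1.94 ± 0.36). Mccc1, a mitochondrial enzyme of leucine breakdown, fell (-2.99 ± 0.48) and Nceh1, a cholesterol ester hydrolase, rose (0.63 ± 0.11); these are the 2 called among 56 tested genes within 10 Mb of Mfn1, Mfn1 itself left out. That is 3.57% of them, against 0.196% elsewhere (odds ratio 18.8, 95% interval 2.09 to 79.7, Fisher's exact p = 0.00624), but it rests on 2 calls that were lost without WT replicate 2. Within 5 Mb, 1 of 38 tested genes was called (Fisher's exact p = 0.0779).

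No list member was called in Mfn1-/- by edgeR, against 76 of 590 at unadjusted p below 0.05 and 14 with DESeq2. The ER unfolded protein response list stood lower (median -0.22; camera adjusted p = 0.000112, and adjusted p = 0.147 with an estimated correlation), with 7 members lower when adjusted over the list alone. Among them were the chaperone Hspa5 at -0.55 ± 0.13 and the disulfide isomerases Pdia4 at -0.47 ± 0.12 and Pdia3 at -0.31 ± 0.08. Cytosolic ribosomal proteins stood slightly lower (median -0.17; camera adjusted p = 0.000618, and adjusted p = 0.379 with an estimated correlation), with 0 members past 0.05 over the list alone. Granulosa markers had a median of -1.36 (camera adjusted p = 0.00471, and adjusted p = 0.532 with an estimated correlation), with Inhba at -3.25 ± 1.08, a marker high in WT replicate 3. In the other lists, 3 genes stood higher over their list alone: the fission and fusion gene Slc25a46 (1.30 ± 0.29), the mRNA decay factor Zfp36l2 (0.80 ± 0.23) and the sphingosine phosphatase Sgpp1 (1.94 ± 0.50). Lower were the deadenylase subunit Cnot7 (-0.53 ± 0.12), the cadherin Cdh1 (-0.40 ± 0.09), the maternal factor Dppa3 (-0.39 ± 0.09), Afg3l2, an inner-membrane protease (-0.42 ± 0.09), Peo1 (Twnk), the mtDNA helicase (-0.80 ± 0.22), Sptlc3 of ceramide synthesis (-1.20 ± 0.31) and the endothelial receptor Kdr (-1.36 ± 0.42).

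Of 11385 genes, 1456 had an unadjusted p below 0.05 in Mfn1-/- against WT, DESeq2 called 224, and 2063 (18.1%) did not overlap between the groups, against 10% by chance. The count was 42 without WT replicate 1, 4 without WT replicate 2, 13 without WT replicate 3, 4 without Mfn1-/- replicate 1, 3 without Mfn1-/- replicate 2, 51 without Mfn1-/- replicate 3, 16 without Mfn2-/- replicate 3 and 46 without Mfn1&2-/- replicate 1. Of 18 named calls only Mfn1 and Chst11 stayed without each library, and the other 16 were lost without WT replicate 2. Losses numbered 5 without WT replicate 1, 16 without WT replicate 2, 12 without WT replicate 3, 16 without Mfn1-/- replicate 1, 15 without Mfn1-/- replicate 2 and 2 without Mfn1-/- replicate 3. Without libraries of the other groups they numbered up to 7.

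The comparison of Mfn2-/- with WT asked what loss of mitofusin 2 alone changed. It changed 1297 genes (515 higher, 782 lower; 11.4% of those tested), 403 of them more than 2-fold and 89 more than 8-fold. With library size alone as the scaling, 49.8% of calls were higher in place of 39.7%. Fam124a, of little-known function, had no count in WT and 27.98 ± 7.02 CPM in Mfn2-/-, at least 338.7-fold more (edgeR adjusted p = 1.64e-06; chromosome 14, 62555737 to 62608486). Btla, an inhibitory receptor of lymphocytes, rose from 0.195 ± 0.210 to 92.1 ± 4.52 CPM (8.83 ± 0.50; chromosome 16, 45224315 to 45257670). Manba, a lysosomal mannosidase, rose from 0.709 ± 0.352 to 48.5 ± 18.4 CPM (6.07 ± 1.18), but stood at 0.25, 0.26 and 19.4 CPM in the Mfn1&2-/- pools. Zbtb7c, a transcriptional repressor, rose by 4.43 ± 0.67. Dhrs3, which reduces retinal, fell from 33.0 ± 9.50 to 0.0777 ± 0.0836 CPM (3 counts in Mfn2-/-; 462.6-fold, counting interval 157.9 to 2246; chromosome 4, 144892827 to 144928209, within 10 Mb of Mfn2). Tie1, an endothelial receptor kinase, fell from 8.95 ± 4.03 CPM to 1 count in the group (373.2-fold, 66.5 to 14786; chromosome 4, 118471191 to 118490061). Pknox2, a homeobox factor, fell from 44.4 ± 7.96 to 0.211 ± 0.258 CPM (-7.78 ± 1.19; chromosome 9, 36890982 to 37147407), and Prr15l, of little-known function, fell by 6.42 on the log2 scale (chromosome 11, 96928104 to 96937830). Of 159 tested genes within 10 Mb of Mfn2, 32 were called (20.1%, against 11.2% elsewhere).

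Cytosolic ribosomal protein genes were mostly lower in Mfn2-/-, with 21 of 74 lower and 1 higher (27 and 4 over the list alone) and a median of -0.33, or -0.29 with library size alone. camera gave adjusted p = 2.65e-06, and adjusted p = 0.287 with an estimated correlation. Rpl37 fell from 248.5 ± 46.1 to 80.5 ± 3.75 CPM (-1.63 ± 0.13), Rpl12 fell (-1.44 ± 0.15) and so did Rpl14 (-1.23 ± 0.14) and Rpl28 (-1.63 ± 0.19). Ribosomal protein genes share reads with their many pseudogenes, and how such reads were counted is not given in the sources used here, so these values are uncertain.

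Mitochondrial genes moved in both directions in Mfn2-/-. Over all genes tested 11.4% were called. The OXPHOS, ER contact, mtDNA maintenance, chaperone and fusion and fission lists held about that share of calls or less. Of 75 nuclear OXPHOS subunits, 5 rose and 4 fell (5 and 5 over the list alone). Cox5b of complex IV fell (-1.04 ± 0.13), as did Atp5b of ATP synthase (-0.58 ± 0.10), while Ndufb5 of complex I rose (1.36 ± 0.22). Ccdc109b (Mcub), which dampens the mitochondrial calcium uniporter, rose from 13.7 ± 4.96 to 76.4 ± 7.19 CPM (2.47 ± 0.48), the only call of the ER contact list. Nrf1, an activator of respiratory genes, fell (-1.34 ± 0.29) as the only call among mtDNA maintenance genes, and Afg3l2 fell (-0.75 ± 0.09) as the only call among mitochondrial chaperones. In the fusion and fission list 1 rose and 1 fell, Mtfr1l falling (-0.53 ± 0.16), and 6 and 1 passed over the list alone; that Mtfr1l call was lost without WT replicate 1, WT replicate 2, Mfn1-/- replicate 1, Mfn2-/- replicates 2 and 3, and Mfn1&2-/- replicates 2 and 3. Among integrated stress response genes, 3 rose and 0 fell (4 and 0 over the list alone; camera adjusted p = 0.279). They included Ddit4, an inhibitor of mTORC1, from 33.5 ± 6.84 to 74.0 ± 5.13 CPM (1.14 ± 0.16). Of 21 ER unfolded protein response genes 0 rose and 4 fell (1 and 5 over the list alone; camera adjusted p = 0.296), among them Canx (-0.59 ± 0.09) and Pdia4 (-0.56 ± 0.12). Autophagy genes had 2 higher and 1 lower, the mitophagy receptor Bnip3l (-0.51 ± 0.10). Of the antioxidant genes 0 rose and 2 fell, with thioredoxin reductase Txnrd1 at -0.94 ± 0.13.

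Of 22 oocyte genes 4 rose and 1 fell in Mfn2-/- (8 and 3 over the list alone), and the list did not pass 0.05 by camera. The growth factor Bmp15 rose (0.50 ± 0.08), as did the secreted Oosp1 (0.54 ± 0.10). Of 27 maternal effect genes 4 rose and 4 fell (4 and 7), with the RNA-binding Zar1l at -1.19 ± 0.18, and of 33 meiotic maturation genes 3 rose and 3 fell (5 and 3). Pde3a, whose breakdown of cAMP releases meiotic arrest, fell (-0.47 ± 0.10). In the mRNA storage list 2 rose and 1 fell (2 and 1), with the uridylyltransferase Zcchc11 (Tut4) at -2.87 ± 0.49. Of 26 adhesion and contact genes 2 rose and 6 fell (2 and 6), among them the cadherins Cdh1 (-0.42 ± 0.09) and Cdh2 (-1.49 ± 0.31) and the formin Daam1 (-1.46 ± 0.24), while Notch2 rose (1.31 ± 0.25). Sphingolipid genes had 4 higher and 1 lower (5 and 1; camera adjusted p = 0.106), among them Kdsr (0.77 ± 0.15) and Sptlc1 (0.44 ± 0.09) of ceramide synthesis. Cholesterol genes had 3 higher and 1 lower, with Hsd17b7 at 0.96 ± 0.17 and Idi1 at -1.11 ± 0.23. Glycolysis genes had 2 higher and 0 lower (4 and 2), with Ldhb at 0.59 ± 0.09. Vesicle genes had 1 higher and 3 lower (3 and 3), PI3K genes 1 and 0, and immediate early genes 0 and 1, the chaperone Dnajb1 (-0.61 ± 0.10). edgeR called 0 apoptosis genes (2 at unadjusted p below 0.05, 1 with DESeq2) and 0 of the 5 markers of endothelium, blood and immune cells (0 unadjusted, 0 with DESeq2). Of 12 granulosa markers 0 rose and 5 fell (median -1.51; camera adjusted p = 0.134), and the calls of Inha (-3.17 ± 0.71) and Inhba (-5.65 ± 1.28) were lost without WT replicate 3. List median and mean, or the direction of camera, differed in sign for the chaperone, maternal effect, mRNA storage, PI3K, apoptosis, autophagy, glycolysis, cholesterol, vesicle and immediate early lists.

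In Mfn2-/- against WT, 3644 tested genes (32.0%) did not overlap between the groups, against 10% by chance, and 1272 of them were called. Without WT replicate 3, 730 genes were called (293 higher, 437 lower), and 670 of the calls stayed. The count was 821 without Mfn2-/- replicate 1, 708 without Mfn2-/- replicate 2 and 759 without Mfn2-/- replicate 3. Apart from Mtfr1l, Inha and Inhba, each gene given here with a call against WT kept it without every library, as did 47 of 82 named calls.

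**Figure D2:**
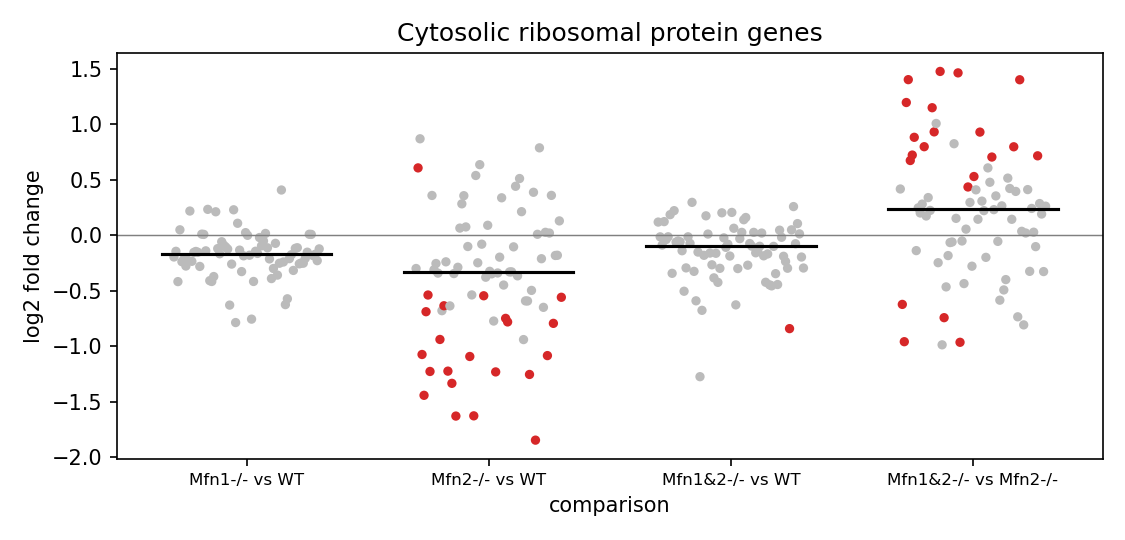
Log2 fold changes of 74 cytosolic ribosomal protein genes in 4 comparisons. Points are genes, red where edgeR's adjusted p was below 0.05 and grey where not, and black lines are medians, which kept their sign against WT in Mfn2-/- (-0.33) and against Mfn2-/- in Mfn1&2-/- (0.24) with library size alone (-0.29 and 0.18).

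The comparison of Mfn1&2-/- with WT asked what loss of both mitofusins changed. It changed 479 genes by edgeR's quasi-likelihood test (239 higher, 240 lower; 4.21%), 242 of them more than 2-fold and 64 more than 8-fold. Cacna1s, a muscle calcium channel, had no count in WT and 109.0 ± 56.9 CPM in Mfn1&2-/-, at least 1377-fold more in pooled counts (chromosome 1, 136052750 to 136119822). Pnpla3, a lipid-droplet lipase, rose from 0.856 ± 0.637 to 212.9 ± 78.7 CPM (7.95 ± 0.47, edgeR adjusted p = 5.14e-08; chromosome 15, 84167837 to 84187236). Cdc5l, a core spliceosome factor, rose from 3.57 ± 1.92 to 292.6 ± 37.6 CPM (6.36 ± 0.33; chromosome 17, 45391884 to 45433737), and Stk32a, a kinase, from 1.11 ± 0.579 to 89.0 ± 2.97 CPM (6.32 ± 0.57; chromosome 18, 43207583 to 43318682). Fam124a rose at least 367.4-fold. Tex15, which acts in germ cell meiosis and silencing, fell from 201.4 ± 71.0 to 8.59 ± 1.00 CPM (-4.56 ± 0.75; chromosome 8, 33516738 to 33585582). Prr18, of little-known function, fell from 40.7 ± 4.60 CPM to 1 count in the group (1637-fold, counting interval 293.4 to 64718; chromosome 17, 8337459 to 8344113). In the Mfn2-/- pools Prr18 stood at 34.9, 0 and 0 CPM. Glt25d2 (Colgalt2), a collagen galactosyltransferase, fell (-5.64 ± 0.47; chromosome 1, 152399830 to 152510695), and Sec16b, an organiser of ER exit sites, fell (-4.08 ± 0.44; chromosome 1, 157506728 to 157568425). Of 159 tested genes within 10 Mb of Mfn2, 18 were called (11.3%, against 4.10% elsewhere).

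List members called in Mfn1&2-/- numbered 11 higher and 14 lower of 590 distinct genes. In the ER contact list 1 rose, Ccdc109b (2.71 ± 0.49), and 1 fell, the tether Rmdn3 (-0.66 ± 0.13). Ccdc109b was at 122.1, 17.8 and 130.0 CPM in the Mfn1&2-/- pools, so 1 pool lay within the WT range, which reached 19.5 CPM. In the fusion and fission list 0 rose and 2 fell (0 and 2 over the list alone). Afg3l2 fell (-0.70 ± 0.09), and Ndufb5 rose as the only OXPHOS call, though not without Mfn1&2-/- replicate 3 (1.07 ± 0.22). Ndufb5 (chromosome 3, 32736990 to 32751566) lies within 10 Mb of Mfn1. Ugcg, which makes glucosylceramide, rose from 88.0 ± 49.4 to 236.5 ± 6.68 CPM (1.43 ± 0.27). Keap1 rose (1.13 ± 0.24) while its target Nfe2l2, the antioxidant regulator NRF2, fell from 21.4 ± 0.740 to 10.7 ± 1.34 CPM; antioxidant calls were 1 higher and 2 lower (3 and 2), and the Nfe2l2 call was lost without Mfn1&2-/- replicate 3. The ER unfolded protein response list had 0 higher and 1 lower (0 and 6; median -0.16; camera adjusted p = 0.00702, and adjusted p = 0.264 with an estimated correlation). Its call was Hspa5 (-0.62 ± 0.13), lost without WT replicate 3 and without Mfn1&2-/- replicate 3. No mtDNA maintenance gene was called by edgeR (3 at unadjusted p below 0.05, 2 with DESeq2), with a list median of -0.24 (camera adjusted p = 0.0236, and adjusted p = 0.272 with an estimated correlation). Granulosa markers had 0 higher and 2 lower (0 and 8; median -1.93; camera adjusted p = 0.00702, and adjusted p = 0.361 with an estimated correlation). Without WT replicate 3, the pool with the high granulosa transcripts, camera gave adjusted p = 0.0841. Kitl, the granulosa ligand of Kit that was not highest in WT replicate 3, fell from 13.0 ± 1.89 to 4.08 ± 0.790 CPM (-1.67 ± 0.29). For integrated stress response genes 2 rose and 0 fell (camera adjusted p = 0.0561), Ddit4 at 0.69 ± 0.16, a call lost without WT replicate 3, Mfn1&2-/- replicate 2 and Mfn1&2-/- replicate 3. Ribosomal proteins had 0 higher and 1 lower (median -0.10; camera adjusted p = 0.0705). edgeR called 0 oocyte list genes (8 unadjusted, 1 with DESeq2) and 0 maternal effect genes (6 unadjusted, 2 with DESeq2).

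In Mfn1&2-/- against WT, 2119 genes had an unadjusted p below 0.05 and DESeq2 called 834. Of the tested genes 2516 (22.1%) did not overlap, against 10% by chance. The count was 301 without WT replicate 2, 282 without Mfn1&2-/- replicate 2 and 297 without Mfn1&2-/- replicate 3. Of 47 named calls, 25 stayed without each library. The Keap1 call was lost without WT replicate 2, WT replicate 3 and Mfn1&2-/- replicate 3.

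**Figure D3:**
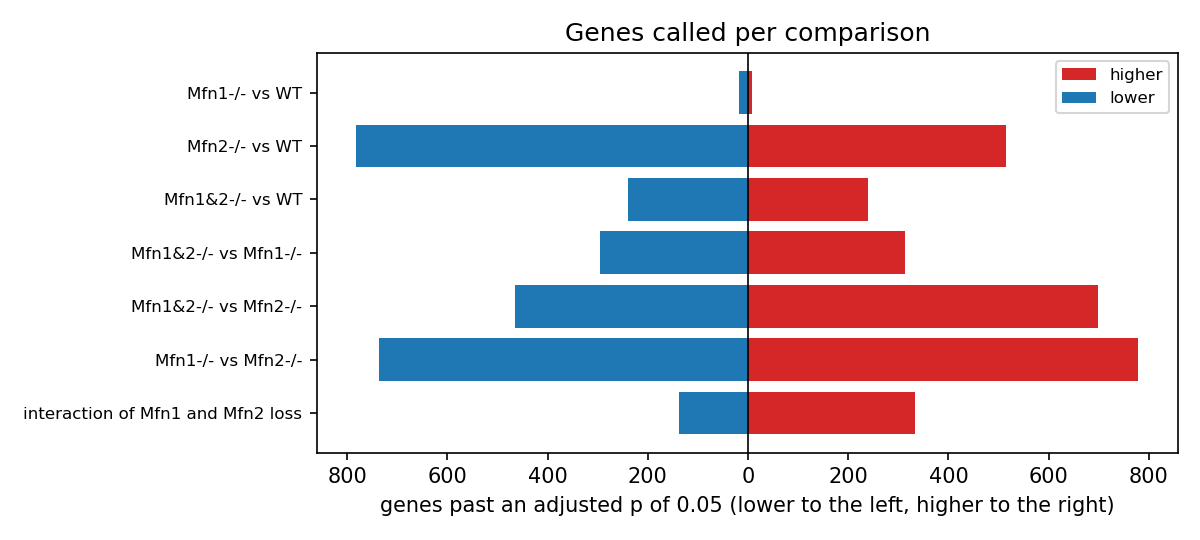
Number of genes called at an adjusted p below 0.05 by edgeR's quasi-likelihood test in 7 comparisons. Bars to the right are genes higher, and bars to the left genes lower, in the group named before the other; with library size alone the share higher in the interaction was 46.3% in place of 70.9%.

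The comparison of Mfn1&2-/- with Mfn1-/- asked what loss of mitofusin 2 changed where mitofusin 1 was already absent. It changed 610 genes by edgeR's quasi-likelihood test (314 higher, 296 lower; 5.36%), or 38.5% higher in place of 51.5% with library size alone. Nfam1, an immune receptor with an ITAM motif, had no count in Mfn1-/- and rose to 18.6 ± 9.70 CPM, at least 267.2-fold in pooled counts (chromosome 15, 82992973 to 83033306). Stk32a rose (8.95 ± 0.70), as did Cdc5l (6.78 ± 0.34), while Dhrs3 fell from 46.9 ± 8.89 to 0.145 ± 0.152 CPM (-8.22 ± 0.48). Dhrs3 lies within 10 Mb of Mfn2, where 26 of 159 tested genes were called (16.4%, against 5.21% elsewhere). Vldlr, a lipoprotein receptor and ATF4 target, rose (1.66 ± 0.35), 1 of 2 stress response calls, both higher (median 0.18; camera adjusted p = 0.0495, and adjusted p = 0.335 with an estimated correlation). In the mRNA storage list 4 rose and 0 fell (8 and 3 over the list alone; median 0.17; camera adjusted p = 0.0495, and adjusted p = 0.335 with an estimated correlation), with Btg4, which drives maternal mRNA decay, at 0.51 ± 0.10. Gpr3, the receptor that maintains meiotic arrest, fell from 46.1 ± 8.02 to 22.0 ± 4.35 CPM (-1.07 ± 0.21). Cd9, a membrane protein needed for fusion with sperm, fell (-1.34 ± 0.18), whereas the sperm receptor Folr4 (Juno) rose (0.60 ± 0.13), a call lost without Mfn1-/- replicate 1. Ugcg rose (1.95 ± 0.27), the cholesterol enzyme Sc5d rose (0.81 ± 0.16), and Rmdn3 fell (-0.82 ± 0.13). mtDNA maintenance genes had 0 calls by edgeR (2 unadjusted, 0 with DESeq2; median -0.19). Markers of endothelium, blood and immune cells had 1, Pecam1, higher (0.46 ± 0.10; lost without Mfn1-/- replicate 1, Mfn1-/- replicate 2 and Mfn1&2-/- replicate 3). Pecam1 stood at 91.5 to 144.65 CPM over all 12 libraries. For both lists camera gave adjusted p = 0.0495, and adjusted p = 0.335 with an estimated correlation. Each list with 0.0495 here stayed below 0.05 in at most 2 of 12 fits with a library left out. edgeR called 0 OXPHOS genes (4 unadjusted, 0 with DESeq2).

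For Mfn1&2-/- against Mfn1-/-, 2963 tested genes (26.0%) did not overlap, against 10% by chance. The count was 295 without Mfn1-/- replicate 1, 352 without Mfn1-/- replicate 2, 377 without Mfn1&2-/- replicate 2 and 389 without Mfn1&2-/- replicate 3. Of 53 named calls, 28 stayed without each library.

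The comparison of Mfn1&2-/- with Mfn2-/- asked what loss of mitofusin 1 changed where mitofusin 2 was already absent. It changed 1163 genes (699 higher, 464 lower; 10.2%), or 48.3% higher in place of 60.1% with library size alone. Pnpla3 rose from 1.52 ± 0.957 to 212.9 ± 78.7 CPM (7.08 ± 0.43), Cdc5l from 5.06 ± 1.65 to 292.6 ± 37.6 CPM (5.83 ± 0.32), and Mll1 (Kmt2a), a histone H3 lysine 4 methyltransferase, from 2.09 ± 0.0420 to 22.3 ± 14.8 CPM (3.41 ± 0.63). Homer2, a scaffold at calcium-release sites, fell from 80.2 ± 14.1 to 9.48 ± 1.26 CPM (-3.08 ± 0.38). Of the ribosomal proteins 17 rose and 4 fell (22 and 5 over the list alone; median 0.24; camera adjusted p = 0.00525, and adjusted p = 0.517 with an estimated correlation), among them Rpl37 (1.47 ± 0.13) and Rpl12 (1.40 ± 0.15). The Mfn2-/- libraries are shared with the comparison against WT, so a gene low in them by chance would fall there and rise here. OXPHOS calls were 6 higher and 3 lower (6 and 4), with Cox5b at 1.10 ± 0.13 and Atp5b at 0.62 ± 0.10. Ugcg rose (2.33 ± 0.27), while the other sphingolipid calls, 5 in all, fell (1 and 7 over the list alone; camera adjusted p = 0.127), with Sptlc1 at -0.42 ± 0.09. Rmdn3 fell (-0.90 ± 0.13), as did Spire1, an actin nucleator that aids fission, (-0.68 ± 0.12). Of the maternal effect genes 6 rose and 4 fell (8 and 5), with Zar1l at 0.96 ± 0.18 and Dppa3 at -0.45 ± 0.09, and of the meiotic genes 4 rose and 3 fell (6 and 6), with the spindle genes Bub1b (0.55 ± 0.10) and Tpx2 (0.62 ± 0.12). Of the antioxidant genes 3 rose and 0 fell, and Ldhb fell (-0.71 ± 0.09). edgeR called 0 mtDNA maintenance genes (5 unadjusted, 1 with DESeq2).

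For Mfn1&2-/- against Mfn2-/-, 3586 tested genes (31.5%) did not overlap, against 10% by chance. The count was 765 without Mfn2-/- replicate 1, 570 without Mfn2-/- replicate 2, 631 without Mfn2-/- replicate 3 and 674 without Mfn1&2-/- replicate 2. Of 74 named calls, 37 stayed without each library.

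The comparison of Mfn1-/- with Mfn2-/- asked how the 2 losses differed. It changed 1515 genes by edgeR's quasi-likelihood test (779 higher and 736 lower in Mfn1-/-; 13.3%), and no list passed 0.05 by camera. Dhrs3 rose from 3 counts in Mfn2-/- to 46.9 ± 8.89 CPM in Mfn1-/- (659.1-fold, counting interval 225.2 to 3199), while Btla fell (-9.46 ± 0.52) and so did Cd200 (-4.61 ± 0.53; chromosome 16, 45382135 to 45409053), a nearby gene for another immune inhibitor. Within 10 Mb of Mfn2, 37 of 159 tested genes were called (23.3%, against 13.2% elsewhere). Of the mRNA storage genes 0 rose and 8 fell (1 and 9 over the list alone; camera adjusted p = 0.135), with Cnot7 at -0.70 ± 0.12 and Marf1, which silences retrotransposons, at -0.53 ± 0.08. Oocyte genes had 2 higher and 8 lower (2 and 9), with Bmp15 at -0.49 ± 0.08 and the linker histone H1foo at -0.39 ± 0.08, and meiotic genes 1 higher and 9 lower (3 and 11), with Fbxo5, an inhibitor of the anaphase-promoting complex, at -0.73 ± 0.14. Of the stress response genes 0 rose and 5 fell (0 and 5; camera adjusted p = 0.244), among them the amino acid transporters Slc7a11 (-0.66 ± 0.12) and Slc7a1 (-0.81 ± 0.15). Of the ribosomal proteins 19 rose and 2 fell (22 and 5; camera adjusted p = 0.135), OXPHOS genes had 5 higher and 7 lower, and Sgms2, a sphingomyelin synthase, fell (-3.70 ± 0.64). edgeR called 0 granulosa markers (0 unadjusted, 0 with DESeq2) and 0 apoptosis genes (2 unadjusted, 1 with DESeq2).

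For Mfn1-/- against Mfn2-/-, 3865 tested genes (33.9%) did not overlap, against 10% by chance. The count was 873 without Mfn1-/- replicate 2, 920 without Mfn2-/- replicate 1 and 965 without Mfn2-/- replicate 3. Of 93 named calls, 60 stayed without each library, among them the genes given here with a value.

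The interaction asked whether the change in Mfn1&2-/- differed from the sum of the changes in Mfn1-/- and Mfn2-/-. It was called for 470 genes by edgeR and 902 by DESeq2. Of the edgeR calls 333 were positive and 137 negative, or 46.3% positive in place of 70.9% with library size alone, a scaling that shifted the median of all genes by -0.11. Stk32a had an interaction of 8.93, Pnpla3 of 6.80 and Cdc5l of 6.25, as these genes rose only where both mitofusins were lost. Glt25d2 had an interaction of -5.28 and Homer2 of -3.63. Ribosomal proteins had 11 positive and 0 negative calls (16 and 1 over the list alone; median 0.44, or 0.32 with library size alone; camera adjusted p = 2.12e-06, and adjusted p = 0.325 with an estimated correlation). The interaction uses the same WT and Mfn2-/- libraries as Mfn2-/- against WT. A list high in WT or low in Mfn2-/- by chance would therefore be positive here. The count was 250 without WT replicate 2, 199 without WT replicate 3, 168 without Mfn1-/- replicate 1, 160 without Mfn2-/- replicate 2, 211 without Mfn2-/- replicate 3 and 228 without Mfn1&2-/- replicate 2. Of 20 named calls, 11 stayed without each library, among them these 5 genes.

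**Figure D4:**
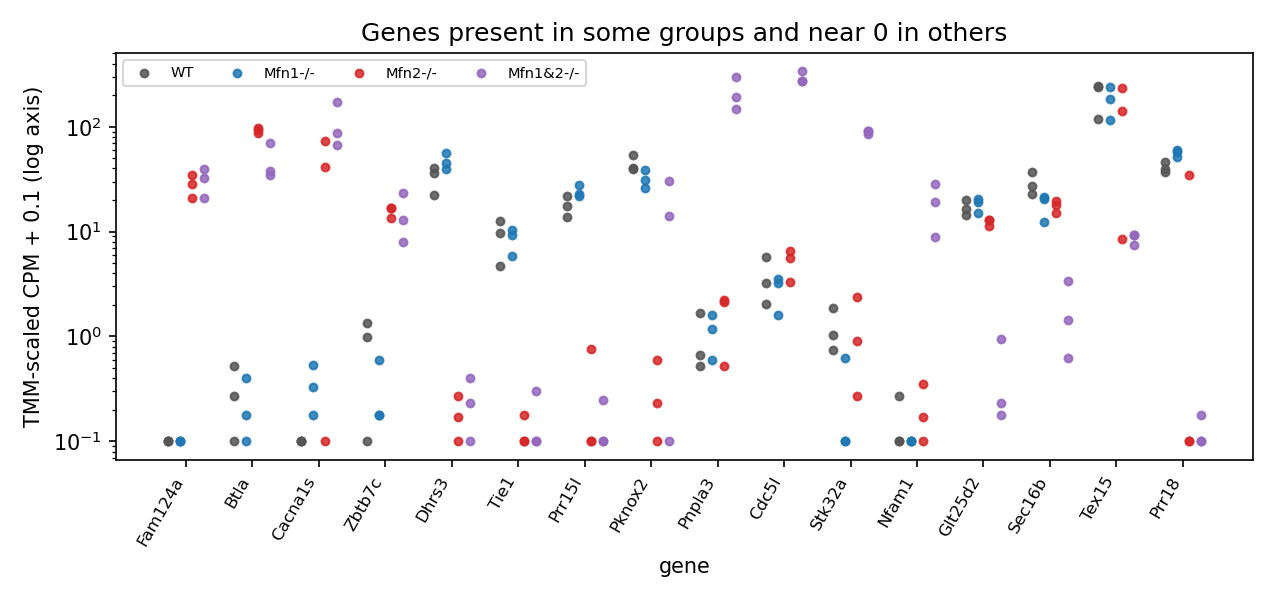
CPM plus 0.1 on a log axis of 16 named genes picked by eye, with points for the 12 libraries by group. Fam124a, Btla and Zbtb7c are high in both groups that lack Mfn2, and Pnpla3, Cdc5l and Stk32a in Mfn1&2-/- alone.

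Changes in Mfn2-/- and in Mfn1&2-/- against WT overlapped, with 117 genes higher in both, 88 lower in both and 3 opposite. Independent draws would give 10.8 and 16.5. Simulated data with no change, in which both comparisons shared a simulated WT group, gave 0. All simulated libraries were drawn from WT mean CPM, so traits of single real WT pools were not in them. With no gene changed, a count near 0 was set in advance, so the simulated counts of shared calls are no benchmark. The covariance of the log2 fold changes was 0.275 against a simulated 0.0621, and their correlation 0.609 against a simulated 0.505. Genes of the same sign made up 64.5%, against a simulated 66.8%. The 3 WT libraries cannot be split into 2 sets of at least 2, so part of the excess may come from the shared controls. Mfn2-/- against WT and Mfn1&2-/- against Mfn1-/-, which share no library, had 97 genes higher in both, 70 lower in both and 13 opposite, against 14.2 and 20.3 by independent draws. Mfn1-/- and Mfn1&2-/- against WT shared 1 higher and 2 lower genes (0.168 and 0.379 by independent draws, simulated 0). Their covariance was 0.104 against a simulated 0.0616, and their correlation 0.323 against a simulated 0.502. Mfn1-/- and Mfn2-/- against WT shared 1 higher and 0 lower (0.362 and 1.24 by independent draws, simulated 0.05). Their covariance stood above the simulated 0.0624 by 0.0376, and their correlation was 0.308 against a simulated 0.506. In both pairs the covariance lay above the simulation and the correlation below it. These values therefore show no clear likeness beyond the shared WT group. Mfn1-/- against WT and Mfn1&2-/- against Mfn2-/- shared 2 and 4 (0.491 and 0.734), with a covariance of 0.00433, inside the simulated range of -0.00315 to 0.00479. The lower genes shared in each pair include a deleted target where both comparisons carry its loss: Mfn2 in the pairs of Mfn2-/- against WT with Mfn1&2-/-, and Mfn1 in the pairs of Mfn1-/- against WT with Mfn1&2-/-. Other genes near a deleted target were not left out of these counts either.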

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

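For the patterns below, the share and odds ratio near Mfn2 and both tests of WT replicate 3 were chosen after the result was seen, while the clustering and ribosomal tests and the chance splits were fixed before; the 6 against 6 fits were added afterwards.

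Many genes changed in Mfn2-/- against WT went from nearly absent to abundant or back, as if variants differed between mouse lines and not only the Mfn2 allele. Only 2.496% of the located calls (95% Clopper-Pearson interval 1.71 to 3.51) lay within 10 Mb of Mfn2, so most calls lay outside that window. A share by position cannot show whether variants carried along with the allele changed genes elsewhere. It therefore does not decide whether they were the whole cause. Within that window the odds of a call were 1.99 times those elsewhere (1.30 to 2.96, Fisher's exact p = 0.00143), so linked variants may account for some of the 32 calls there. The odds ratio in that window was 2.98 for Mfn1&2-/- against WT and 3.56 for Mfn1&2-/- against Mfn1-/-, so the same limit holds there. It was 1.99 for Mfn1-/- against Mfn2-/-. For Mfn1&2-/- against Mfn2-/-, where both groups lack Mfn2, it was 0.917. Outside the windows, 44 pairs of genes changed at least 4-fold lay within 2 Mb, against a median of 29 (21 to 39) for random sets of the same expression, as unlinked variants between the lines could give, though genes regulated together could cluster too. Some genes had pools of the same group under 1 and at least 10 CPM, at least 16-fold apart (10 in WT, 6 in Mfn1-/-, 11 in Mfn2-/-, 9 in Mfn1&2-/-), some of them graded over the pools, and genotypes of the pools at other loci would be needed to tell.

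Granulosa transcripts in WT replicate 3 had 9 of 12 markers at their highest value of the 12 libraries. The library was singled out by these same markers, so the count restates the pattern, and whether RNA of granulosa cells in that pool accounts for it stays open. Without that library 627 calls of Mfn2-/- against WT were lost. Of these, 59.0% (55.0 to 62.9) were lower in Mfn2-/-, close to the 60.3% of all calls. A smaller sample also loses calls in both directions, as without Mfn2-/- replicate 2 (279 higher and 429 lower left). The share lower therefore cannot show how far granulosa RNA caused the loss.

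Cytosolic ribosomal proteins lower in Mfn2-/- against WT had a median of -0.33. Random lists matched on GC content had a median of 0.0170 (-0.08 to 0.12), so GC content alone does not account for it. With library size only the list itself had -0.29 (bootstrap standard error 0.057), so neither does the TMM scaling. Random lists matched on transcript length had a median of 0.0229 (-0.11 to 0.14). Their median length was 1184 bases, against 1076.4 for the ribosomal list. Lengths were not measured for the transcripts made in oocytes, so an effect of short transcripts stays open. Length and GC content were matched separately, and their joint effect was not tested. Reads shared with pseudogenes remain open and could be tested only from the alignments.

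Grouping by chance was tested by other splits of the same libraries. For the pairwise comparisons only 10 splits exist, too few for a share under 0.05; in each case 1, the real grouping, called as many genes as the real value. The highest other split called 0 for Mfn1-/- against WT (26), 0 for Mfn2-/- against WT (1297), 1 for Mfn1&2-/- against WT (479), 1 for Mfn1&2-/- against Mfn1-/- (610), 4 for Mfn1&2-/- against Mfn2-/- (1163) and 0 for Mfn1-/- against Mfn2-/- (1515). For the interaction, 1 of 100 splits, the real grouping, called as many as 470, and the highest other called 10. In fits of 6 against 6, Mfn2 loss called 667 genes (351 higher, 316 lower) and Mfn1 loss 13 (6 higher, 7 lower). In each, 1 of 100 splits, the real grouping, called as many, with 10 in the highest other. These splits mixed groups that differ, which widens the spread within the new groups and lowers their calls. They therefore cannot show how many calls would arise with no interaction or no effect of the loss.

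The interaction was called for 470 genes in these groups with edgeR and 902 with DESeq2, and variants between the lines were not excluded for them. Of all interaction calls, 27 were over 8-fold, and not all of them are named here. Among calls with a named symbol and a mean of at least 5 CPM in some group, the largest positive interactions were Stk32a 8.93, Pnpla3 6.80, Pknox2 6.67, Nap1l5 6.30, Cdc5l 6.25, Lrmp 3.80, Tnc 3.66, Cttnbp2 3.38, Tekt4 3.35 and Abca9 3.07. Within the same rule, the largest negative interactions were Glt25d2 -5.28, Ublcp1 -4.48, D5Ertd577e -4.43, Tex15 -3.73, Homer2 -3.63, Psmb5 -2.85, Rnaset2b -2.78, Sec16b -2.68, Hgsnat -2.43 and Enpp4 -2.12. Nap1l5 is a granulosa marker, at 38.75 CPM in WT replicate 3 and at 2.00 and 5.65 CPM in the other WT pools, and its interaction was not called without WT replicate 3. Pknox2 stood at 0, 13.9 and 30.1 CPM in the 3 Mfn1&2-/- pools.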

How the results depend on the processing

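The number of genes called Mfn1-/- against WT was 26, and depended most on the choices made. It was 224 with the DESeq2 Wald test, 13 with only the groups compared and 1 with the 1.5-fold threshold (glmTreat), and ran from 3 to 51 as each library was left out. For Mfn2-/- against WT (1297) the 1.5-fold threshold left 127, and leaving out libraries gave 708 to 1429. For Mfn1&2-/- against WT (479) the DESeq2 Wald test gave 834, the threshold 93 and left-out libraries 282 to 550. For Mfn1&2-/- against Mfn1-/- (610) these were 1044, 127 and 295 to 689. For Mfn1&2-/- against Mfn2-/- (1163) limma-voom with quality weights gave 1962, the threshold 62 and left-out libraries 570 to 1302. For Mfn1-/- against Mfn2-/- (1515) the threshold left 166 and left-out libraries gave 873 to 1673. For the interaction (470) DESeq2 gave 902, the threshold 27 and left-out libraries 160 to 464. The fit with only the groups compared was not run for the interaction. The threshold asks a stricter question by construction, and the cause of the other differences was not tested.

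Keeping genes without a filter changed nothing, since filterByExpr had removed none. RLE scaling gave 23 to 1497 genes over the 7 comparisons and library size only 26 to 1548, with the shares of higher genes moved as printed in the report. limma-voom gave 19 to 1642, and the filter at 5 CPM 27 to 1548. Without genes within 10 Mb of Mfn1 or Mfn2, chosen after seeing the data, 1248 genes were called for Mfn2-/- against WT, 1238 of them also called with all genes, and 20 for Mfn1-/- against WT.

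Replicate numbers in the titles do not pair the pools as far as the labels say. With the number as a replicate block, the interaction called 276 genes and the other comparisons 21 to 1331. The 18 pairs with the same number in different groups correlated at -0.13 to 0.18 after group means were removed. With the block, 45 of 421 gene values lost their call. The block uses residual degrees of freedom, so fewer calls do not mean a smaller effect.

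Of 421 gene values, the call was lost for 5 with RLE, 18 with library size only, 4 of 415 with DESeq2, 49 with limma-voom, 41 with quality weights, 51 of 400 with only the groups compared, 253 with the 1.5-fold threshold and 7 of 397 without the genes near Mfn1 or Mfn2. Over 5052 values with a library left out, 775 calls were lost and 2 signs reversed, each of an uncalled target. Mfn1 in Mfn1&2-/- against Mfn1-/- (0.14) was -0.10 without Mfn1&2-/- replicate 1 and 0.32 without Mfn1&2-/- replicate 3. Mfn2 in Mfn1&2-/- against Mfn2-/- (-0.05) was 0.12 without Mfn2-/- replicate 3 and -0.18 without Mfn2-/- replicate 1.

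With the inter-gene correlation estimated, no list kept an adjusted p below 0.05 with camera. The values were 0.147, 0.379 and 0.532 for ER unfolded protein response, ribosomal and granulosa lists in Mfn1-/- against WT, and 0.287 for ribosomal proteins in Mfn2-/- against WT. In Mfn1&2-/- against WT they were 0.264, 0.361 and 0.272 for ER unfolded protein response, granulosa and mtDNA maintenance lists. In Mfn1&2-/- against Mfn1-/- all 4 lists had 0.335, and ribosomal proteins had 0.517 against Mfn2-/- and 0.325 in the interaction. The same 4 lists had 0.0610 with RLE, and with the replicate block 0.0901 for stress response, mtDNA maintenance and endothelium and 0.103 for mRNA storage. As libraries were left out they ran up to 0.186 (stress response), 0.11 (mtDNA maintenance), 0.146 (endothelium) and 0.158 (mRNA storage). Of 12 such fits, camera's adjusted p was below 0.05 in 1 for stress response and in 2 for each of the others. The mtDNA list in Mfn1&2-/- against WT reached 0.0831 without WT replicate 3 and 0.0677 without Mfn1&2-/- replicate 2, and the granulosa list 0.0841 without WT replicate 3. The other lists stayed below 0.05 without each library.

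Depth limits genes near the floor: a group with 0 counts gives only a lower bound of the fold change, and groups with 1 to 3 counts give intervals such as 66.5 to 14786 for Tie1.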

Other observations

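These genes were picked after their values were seen. Ccdc109b (Mcub), of mitochondrial calcium uptake, was called in both groups that lack Mfn2, at 2.47 and 2.71 against WT, though the Mfn1&2-/- pools overlapped WT, and Cacna1s reached 109.0 CPM in Mfn1&2-/- while its Mfn2-/- pools stood at 0, 41.4 and 72.4 CPM. Rmdn3, which tethers mitochondria to the ER, was lower in Mfn1&2-/- than in every other group (-0.66, -0.82 and -0.90) and was not called for either loss alone.

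Cd9 and Folr4 (Juno) of the adhesion and contact list moved in opposite directions in Mfn1&2-/- against Mfn1-/-. Cd9 was at -1.34 there and at -1.23 against Mfn2-/-. Folr4 was at 0.60 there and at 0.47 against WT, and its call against Mfn1-/- was lost without Mfn1-/- replicate 1. Values of Cd9 against WT and of Folr4 against Mfn2-/- are not given here, and these genes do not stand for the whole list. These genes too were picked after their values were seen.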
